A study of Mus musculus with 5 samples.

How the data were processed

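RNA-seq libraries were made from mouse embryos at the 2-cell stage. Per the labels' protocols, oocytes of hormone-stimulated females were fertilised in vitro for about 6 h, fertilised eggs were cultured for 24 h in KSOM medium with 25 nM PNMC or the same volume of DMSO, total RNA was extracted with TRIzol, and libraries were made with Smart-seq2, which copies polyadenylated RNA and keeps no strand information. Reads of overlapping genes on opposite strands can therefore not be told apart. The submitters' processing notes name Trimmomatic, HISAT2 2.0.5, HTSeq, DESeq2 1.16.1 and the build GRCm39. The annotation, and which tool made the deposited values, are not given in the sources used here.

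The authors deposited 1 table of 32285 gene symbols with a normalised signal per library and no identifiers or coordinates. Its unit is not stated. The values are fractional, never negative, and sum to between 446010 and 454548 in every library, so they are neither raw counts nor a unit that sums to 1000000 over these genes. Sums of this size would suit a unit scaled by gene length and depth. Low values showed no common step from which whole reads could be recovered, so the depth is unknown, no count test was run and no counting interval is given. Values at 0 may be undetected or failed estimates. Of the symbols, 11 read as calendar dates, as spreadsheet software writes the March gene family, and 10000 were at 0 in every library. The reference at hand was GENCODE release M21 on another build, so no coordinates are given. It holds 31413 of the table's symbols, and it was used only for transcript lengths and shared sequence. Each column was matched to its sample by the sample's title.

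The following was computed from those values, with R 4.3.3, limma 3.58.1, Python 3.11.15 and scipy 1.17.1. Genes with a value of at least 1 in at least 2 of the 5 libraries were kept, which left 12734 and removed 19551. Values were transformed to log2(value + 1), and 3 PNMC libraries were compared with 2 controls by limma's moderated test with a mean-variance trend and robust variances, with no covariate. P-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Means are given with SDs over 2 control and 3 PNMC libraries, and SEs and 95% intervals are limma's. The design was written for counts or for normalised values, and the second branch applied.

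The 28 gene lists were fixed before the data were examined. They hold 1490 names, and 1236 genes were tested. They cover the 2-cell programme, regulators of genome activation, oocyte transcripts, ribosomal proteins and biogenesis, proteasome, splicing, mitochondria, redox, repair, p53, apoptosis, autophagy, DNA methylation, histone enzymes, xenobiotic metabolism, stress, heat shock, cell cycle, lineage, energy and lipid metabolism, and markers of cumulus cells, sperm, blood and oviduct. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists. The median, mean and direction of the test differed in sign in 10 lists, none of them among the 4 that passed. Genes named in the text were chosen by a rule: the 6 of each direction with the largest change among those past the threshold that had no overlap between groups and a mean of at least 5 or, since none passed, the 6 of each direction with the smallest p, then the 2 members of each list with the smallest p, and Actb and Gapdh. A gene that the rule names is not reported here. Genes outside the rule are the most abundant ones and those said to be chosen after their values were seen. Reads of multicopy families such as Zscan4, Usp17l, Obox, Oog and ribosomal proteins could be split between near-identical copies, and their values are uncertain for that reason.

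The procedure was tested on data simulated with the real genes' means, limma's moderated variances and normally distributed noise. In 20 simulated datasets of 12734 genes, 200 genes with a mean log2 value of at least 4 were changed. The calls held 87.5% of the 2-fold changes, 100% of the 4-fold changes, 99.8% of the 8-fold changes and 0.108% of unchanged genes. With 200 changed genes the adjusted threshold is easier to pass than with few. These shares may therefore overstate the power where few genes change. For changed genes they cover only those with a mean log2 value of at least 4. The median of the tested genes was lower, from 2.958 to 3.085 across the libraries. A list shift of -0.3 in the ribosomal protein genes was called in 20 of 20 datasets. Genes were drawn independently of each other there, so the simulation does not describe lists whose members vary together. The simulated shift was also larger than the median changes of the lists that passed in the real data, from -0.196 to 0.0469. Power at those sizes was not simulated.

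Alternatives were a pseudocount of 0.1, no filter, a minimum of 10 in 2 libraries, quantile and median scaling, the replicate number as a block, each library left out in turn (a lone control is then assumed to vary like the PNMC libraries), fry, and camera with an estimated correlation. A limma fit without the variance trend and the robust step, and the use of every alternative on the count at an unadjusted p, were added after the data were seen.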

Results

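Gene expression was measured by RNA-seq in mouse embryos at the 2-cell stage, the stage at which the embryo begins large-scale transcription of its own genome. Embryos fertilised in vitro were cultured for 24 h with 25 nM PNMC or with the same volume of the solvent DMSO. The labels do not spell out the abbreviation PNMC. There were 3 PNMC libraries and 2 control libraries, and the single comparison asked which transcripts differed with the exposure. Nothing in the labels says whether the libraries came from separate cultures or how many embryos each held, so the p-values measure only the spread between these libraries, which may be technical. Values were normalised expression levels whose unit is not given in the sources used here, and the read depth behind them is unknown. They summed to 446466 and 447155 in control libraries 1 and 2, and to 446010, 452811 and 454548 in PNMC libraries 1, 2 and 3. Control library 2 listed 18595 genes above 0, against 17635 in control library 1 and 17608, 17408 and 17542 in the PNMC libraries.

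Oocyte and maternal transcripts made up most of the highest levels in both groups. Zbed3 averaged 12307 ± 326 (SD, n = 2) in controls and 13081 ± 1408 (SD, n = 3) after PNMC. Tcl1, an AKT co-activator abundant in oocytes, averaged 5588 ± 84.0 and 6458 ± 213. Btg4, an adaptor of maternal mRNA decay, averaged 3486 ± 122 and 3611 ± 268, and Dppa3, a maternal factor that protects DNA methylation, averaged 3107 ± 76.3 and 3296 ± 157. The mitochondrial transcript mt-Cytb averaged 10716 ± 299.5 and 10188 ± 829. Genes of the transient 2-cell programme were also present in every library. Zscan4d, a telomere regulator of that programme, averaged 158 ± 4.74 in controls and 159 ± 35.2 after PNMC, and the zinc finger gene Zfp352 averaged 282.6 ± 70.4 and 254.1 ± 22.6. Zscan4d and Zfp352 were chosen as examples after their values were seen. The libraries did not group by exposure: the mean Pearson correlation of log2 values was 0.9616 over the 4 pairs within a group and 0.9608 over the 6 pairs between groups.

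No gene rose or fell with PNMC at an adjusted p under 0.05 among the 12734 genes tested with limma, and the lowest adjusted p was 0.172. At an unadjusted limma p under 0.05 there were 636 genes, of which 220 were higher and 416 lower after PNMC, where 5% of the genes tested is 637. The 3 PNMC values lay entirely above or entirely below both control values in 2534 genes, or 19.9%, where chance gives 20%. Of the genes at the unadjusted threshold, 34.6% were higher in PNMC, a share that became 50.6% under quantile normalisation, 59.0% after scaling to the median and 51.2% without control library 2.

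The 12 genes with the smallest p in the 2 directions did not pass the adjusted threshold, and their values are given as measured. Among those with higher values, AU022751, an abundant transcript, averaged 1683 ± 88.0 (SD, n = 2) in controls and 2344 ± 129 (SD, n = 3) after PNMC, a log2 change of 0.48 (SE 0.0858, limma adjusted p = 0.206). Oog3, of the oocyte-specific oogenesin family, averaged 3167 ± 568 and 4154 ± 104, a log2 change of 0.40 (SE 0.097, limma adjusted p = 0.731). Rnf212, known for its part in meiotic crossing over, averaged 0.965 ± 0.960 and 5.44 ± 0.207, and Etfbkmt, a mitochondrial lysine methyltransferase, averaged 4.39 ± 0.0658 and 10.96 ± 2.77. The predicted gene Gm47003 was listed at 0 in both controls and at 3.81, 3.60 and 3.13 in the PNMC libraries, and Gm49494 averaged 0.0361 and 2.53. Among those with lower values, Gm13103 averaged 58.6 ± 23.3 in controls and 14.5 ± 8.29 after PNMC, a log2 change of -2.01 (SE 0.348, limma adjusted p = 0.172). Gm9 averaged 28.1 ± 7.07 and 7.70 ± 2.75, Gm13089 averaged 17.4 ± 6.45 and 3.97 ± 1.45, and Gm6871 averaged 20.6 ± 3.11 and 7.81 ± 0.585. Rhbdl2, a rhomboid protease gene, averaged 5.24 ± 0.323 and 0.578 ± 0.375, and the immunoglobulin constant gene Ighg2b averaged 28.2 ± 13.8 and 9.43 ± 0.850. Without PNMC library 1, Gm13103 was the only gene past the threshold (log2 change -2.42, limma adjusted p = 0.00537).

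**Figure D1:**
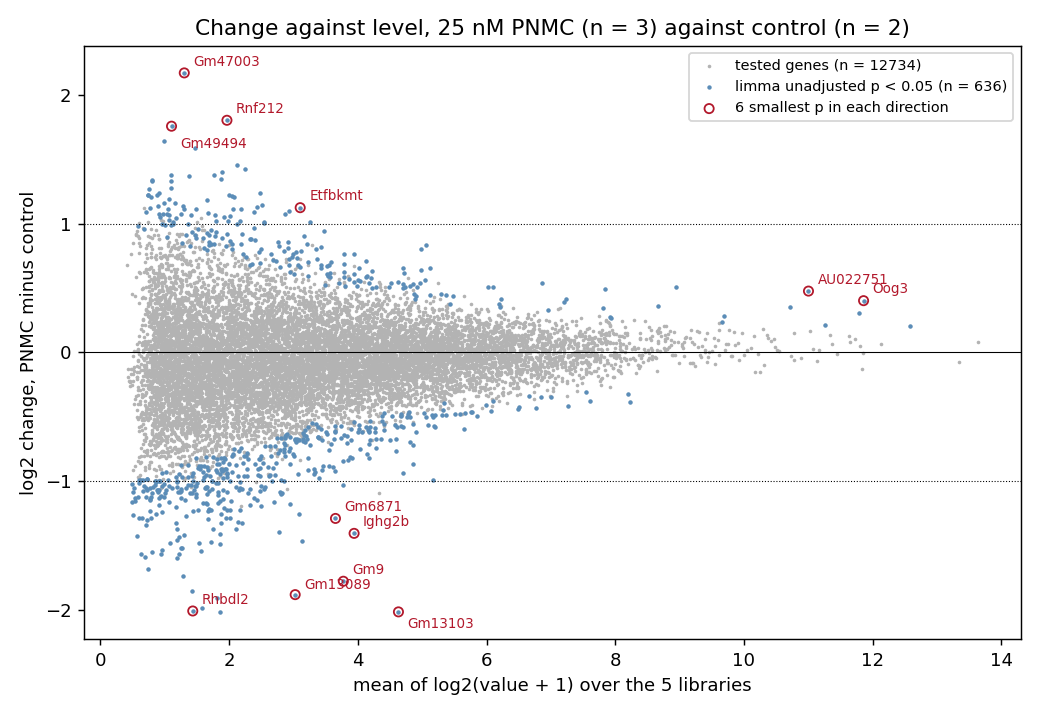
Log2 change (PNMC minus control, log2 of value + 1) against the mean log2 level for each of the 12734 tested genes. Blue points have an unadjusted limma p under 0.05, and red circles mark the 6 genes with the smallest p in each direction. Dotted lines mark a 2-fold change in value + 1. The scatter narrows with level, and no point passes an adjusted p of 0.05.

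**Figure D2:**
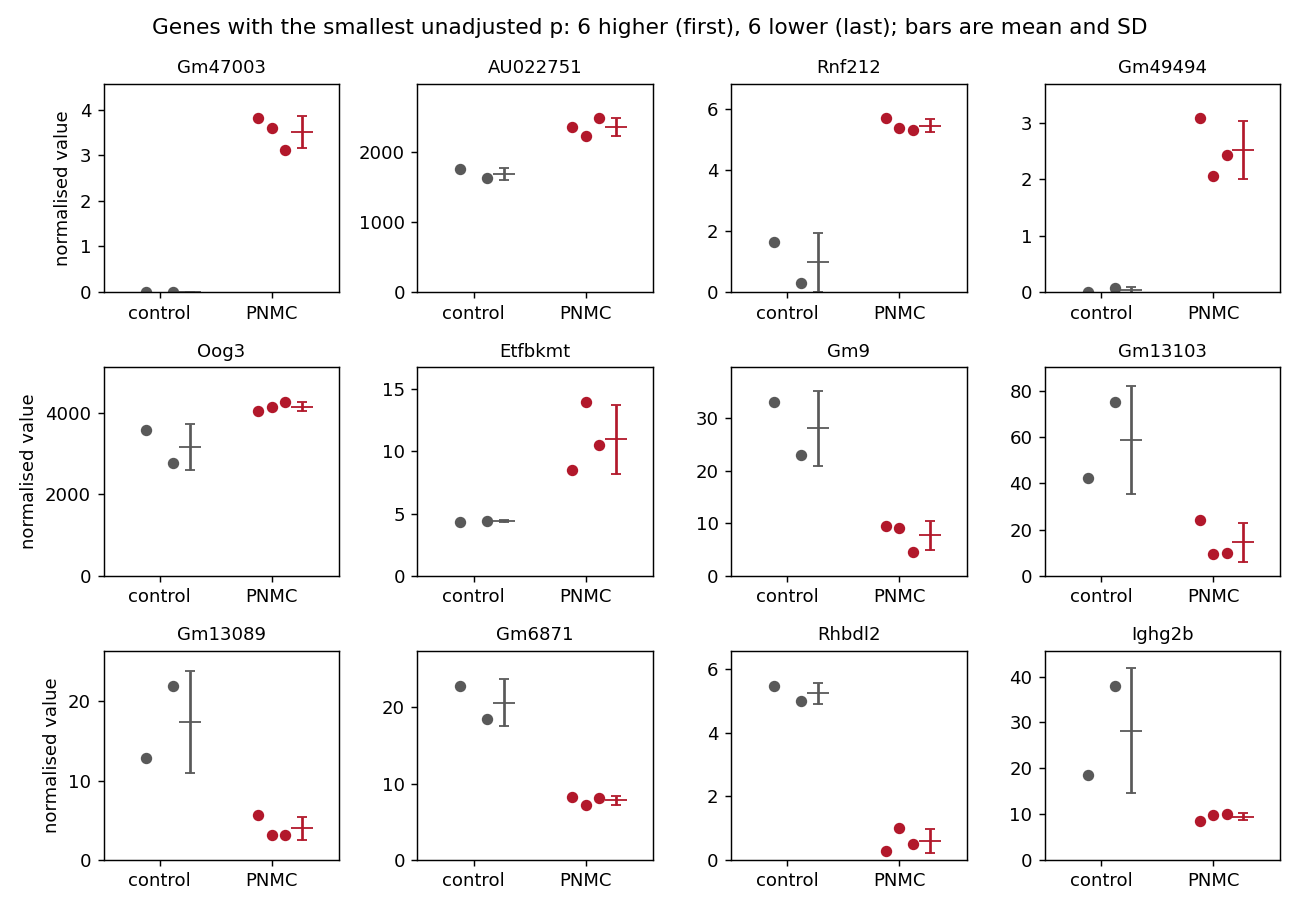
Normalised value in each library for the 6 higher and 6 lower genes with the smallest unadjusted p; points are libraries, horizontal marks and bars are the mean and SD, and each vertical axis starts at 0. The PNMC points lie apart from the control points in all 12 genes, none of which passed the adjusted threshold. The genes were picked for their small p, which favours such separation. Over all tested genes 19.9% lay apart in this way, where chance gives 20%.

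The intervals bound how large a change these libraries leave open. The 95% confidence interval of the log2(value + 1) change lay within 1 unit in either direction for 7814 genes, or 61.4% of those tested. The bound is close to a 2-fold change for abundant genes, but it allows a larger change in low genes. Such genes within the bound made up 99.9% of the 750 genes with a mean level of at least 100. The share was 97.8% of the 2794 genes from 20 to 100, 76.8% of the 3850 genes from 5 to 20, and 25.8% of the 5340 genes under 5. For example, the interval for Zscan4d ran from -0.37 to 0.34 and that for the cytoskeletal reference Actb from -0.63 to 0.19. Gapdh, another common reference, was near the floor of the table in both groups, at 1.36 ± 0.0197 in controls and 1.21 ± 0.188 after PNMC.

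Of 28 gene lists fixed before the data were examined, 4 passed camera's test at its preset correlation of 0.01. Ribosomal proteins, respiratory chain subunits and stress response genes shifted lower, and oocyte and maternal transcripts shifted higher relative to other genes, a call that ended under quantile normalisation (median -0.01, camera adjusted p = 0.862). None of the 4 passed with an estimated correlation, where the adjusted p was 0.971 for each, or with fry, whose lowest adjusted p was 0.214. With an estimated correlation camera rests on the 3 residual degrees of freedom, and its power was not simulated. The stress response list's camera p rose from 0.00457 to 0.0439 there, though its estimated correlation was -0.00348, below the preset. For the stress response list, the call lost in that setting is therefore weak evidence against a shift. The estimated correlation was 0.455 for ribosomal proteins, 0.262 for the respiratory chain and 0.0529 for the maternal list, all above the preset. Their calls at the preset therefore took too little account of how far the members varied together. No single member of any list passed, whether adjusted over all genes or adjusted over the list alone.

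Among the 82 ribosomal protein genes, 60 had lower and 22 higher mean log2 values after PNMC, with a median log2 change of -0.15 (camera adjusted p = 0.0146; adjusted p = 0.971 with an estimated correlation). Rpl18 averaged 37.4 ± 3.91 and 19.3 ± 3.77, and Rps23 averaged 45.04 ± 4.45 and 30.8 ± 8.84. The mean deviation of the list from each gene's average was 0.14 and 0.06 in the controls and -0.10, 0.23 and -0.32 in PNMC libraries 1, 2 and 3, so PNMC library 2 lay above both controls. Without PNMC library 3 the median was -0.01 (camera adjusted p = 0.976). The call also ended without control library 1 (camera adjusted p = 0.696) and without PNMC library 1 (camera adjusted p = 0.102), and with 1 library left out the adjusted p ranged from 5.86e-11 to 0.976. It also ended after median scaling (median -0.08, camera adjusted p = 0.0588), with no filter (camera adjusted p = 0.11) and under the replicate block (median -0.01, camera adjusted p = 0.966).

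Among the 78 nuclear-encoded respiratory chain and ATP synthase genes, 60 had lower and 18 higher values, with a median log2 change of -0.20 (camera adjusted p = 0.0146; adjusted p = 0.971 with an estimated correlation). Uqcrb, of complex III, averaged 5.94 ± 0.343 and 2.45 ± 1.05. Control library 2, which listed the most genes, had the highest level of this list (0.28) and PNMC library 3 the lowest (-0.30). Without control library 2 the median was -0.11 (camera adjusted p = 0.803) and without PNMC library 3 it was -0.09 (camera adjusted p = 0.858), where the range with 1 library left out was 1.85e-05 to 0.858. The call also ended with no filter (camera adjusted p = 0.0767) and under the replicate block (camera adjusted p = 0.917). The 13 protein-coding mitochondrial genes had a median log2 change of -0.04 (camera adjusted p = 0.871), with mt-Nd2 at 1299 ± 66.6 and 1174 ± 158 and mt-Nd1 at 3864 ± 92.96 and 3559 ± 457. That list passed without PNMC library 2 (median -0.12, camera adjusted p = 0.0202) and under quantile normalisation (median -0.13, camera adjusted p = 0.00548), and its median was 0.03 after median scaling.

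Among the 41 genes of the unfolded protein and integrated stress response, 27 had lower and 14 higher values, with a median log2 change of -0.14 (camera adjusted p = 0.032; adjusted p = 0.971 with an estimated correlation). Ddit3, the stress-induced transcription factor CHOP, averaged 32.0 ± 2.99 and 21.1 ± 2.70, a log2 change of -0.58 (SE 0.204, limma adjusted p = 0.967). Sdf2l1, an endoplasmic reticulum chaperone cofactor, averaged 22.2 ± 0.462 and 14.3 ± 2.30. Hspa5, the main chaperone of that compartment, averaged 132 ± 5.42 and 104 ± 7.19 and was named after its values were seen. The mean deviation of the list was 0.08 and 0.13 in the controls and -0.08, -0.05 and -0.08 in the PNMC libraries, so all 3 PNMC libraries lay below both controls. The glycolysis and citric acid cycle list and the sperm and blood and immune markers also lay lower in all 3 PNMC libraries, which makes 4 of the 28 lists without overlap between groups, or 14.3%, where chance gives 20%. The call ended without control library 1 (median -0.12, camera adjusted p = 0.313), without PNMC library 1 (median -0.18, camera adjusted p = 0.143) and without PNMC library 3 (median -0.12, camera adjusted p = 0.0939), over a range from 0.0226 to 0.313 with 1 library left out. It also ended after median scaling (median -0.06, camera adjusted p = 0.0894), with no filter (median -0.14, camera adjusted p = 0.0767) and under the replicate block (median -0.12, camera adjusted p = 0.138).

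Among the 97 oocyte and maternal genes, 57 had higher and 40 lower values, with a median log2 change of 0.05 against -0.05 over all tested genes (camera adjusted p = 0.0146; adjusted p = 0.971 with an estimated correlation). Besides Oog3, E330034G19Rik averaged 3108 ± 26.8 and 3848 ± 349. The mean deviation of the list was -0.0798 and 0.0574 in control libraries 1 and 2 and 0.047, -0.0151 and -0.00949 in PNMC libraries 1, 2 and 3. Control library 2 thus lay above every PNMC library, and only control library 1 lay below them. The median was -0.01 without control library 1 (camera adjusted p = 0.696), and the call also ended without PNMC library 1 (camera adjusted p = 0.143), over a range of adjusted p from 0.00118 to 0.696 with 1 library left out. It also ended with no filter (camera adjusted p = 0.0767) and under the replicate block (camera adjusted p = 0.0961).

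**Figure D3:**
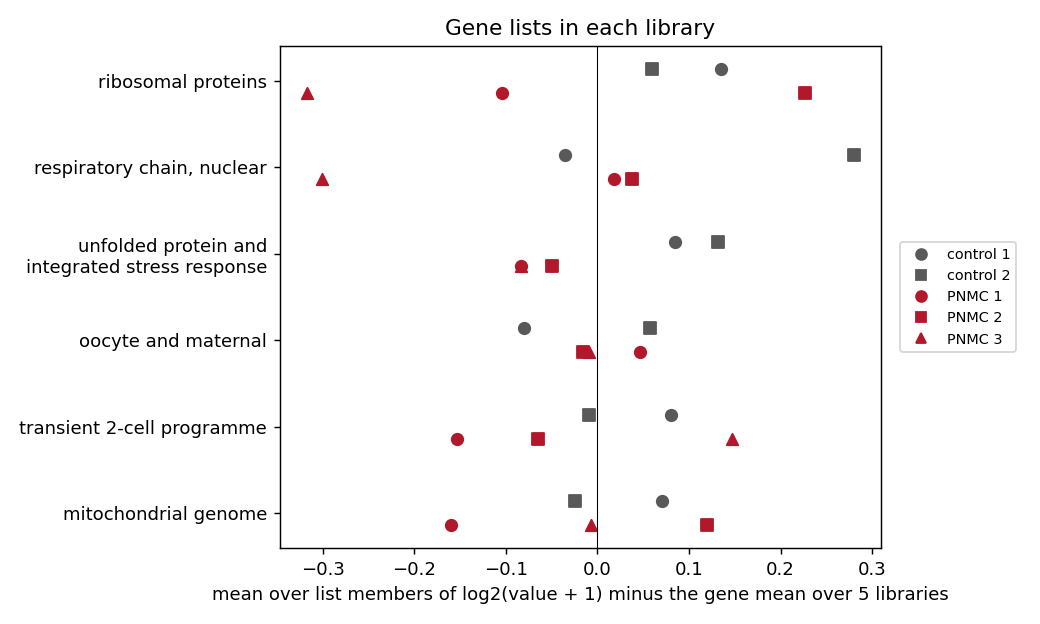
Mean over the members of 6 gene lists of log2(value + 1) minus each gene's mean over the 5 libraries, 1 point per library; grey marks controls, red marks PNMC, and the symbol gives the library number. Ribosomal proteins spread from -0.32 to 0.23 within the PNMC group, while the stress response list separates the groups by a smaller distance.

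None of the lists tied to genome activation and lineage passed. The 42 tested genes of the transient 2-cell programme had a median log2 change of -0.06 (camera adjusted p = 0.871), which passed without PNMC library 3 (median -0.12, camera adjusted p = 0.0337) and was 0.01 after median scaling. Their 2 members with the smallest p were Gm12794, at 93.7 ± 4.66 and 80.2 ± 5.14, and Gm21761, at 41.9 ± 2.87 and 33.7 ± 11.1. The 33 regulators of genome activation had a median of 0.05 (camera adjusted p = 0.391), with the homeobox gene Obox5 at 1161 ± 3.09 and 1318 ± 60.7 and the retinoic acid receptor Rarg at 14.2 ± 0.843 and 9.91 ± 1.76. Ribosome biogenesis factors had a median of -0.11 over 112 genes (camera adjusted p = 0.156), with Rsl24d1 at 148 ± 19.9 and 116 ± 6.30 and the helicase Ddx47 at 47.7 ± 6.36 and 35.3 ± 9.48. That list passed without control library 2 (median -0.21, camera adjusted p = 1.47e-05) and without PNMC library 2 (median -0.16, camera adjusted p = 0.0101), and its median was 0.00428 without control library 1. Pluripotency and lineage factors had a median of 0.00436 over 28 genes (camera adjusted p = 0.871), with Zfp42 at 9.48 ± 1.19 and 5.27 ± 0.637 and Utf1 at 1.91 ± 2.33 and 4.73 ± 1.39.

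Damage and death pathways did not pass either. Antioxidant genes had a median of -0.05 over 55 genes (camera adjusted p = 0.871), and within the list the metallothionein Mt2 averaged 53.6 ± 2.26 and 27.4 ± 9.07 (limma adjusted p = 0.731), while Gstz1 averaged 2.11 ± 2.32 and 6.08 ± 0.207. The xenobiotic list had 18 of its 51 genes above the filter and a median of -0.11 (camera adjusted p = 0.871), with Cbr1 at 7.36 ± 0.385 and 4.38 ± 2.41 and Ephx2 at 2.45 ± 1.46 and 0.879 ± 0.602. DNA repair genes had a median of -0.01 over 78 genes (camera adjusted p = 0.871), with Xrcc1 at 8.43 ± 2.56 and 3.87 ± 1.07 and Xpa at 6.40 ± 3.48 and 2.66 ± 0.975. The p53 target list had a median of -0.10 over 21 genes (camera adjusted p = 0.299), with Ei24 at 58.8 ± 17.1 and 41.0 ± 2.30 and Ercc5 at 21.2 ± 5.30 and 14.0 ± 5.55. The p53 list passed without control library 2 (median -0.21, camera adjusted p = 0.0493) and under the stricter filter (median -0.18, camera adjusted p = 0.026). Apoptosis genes had a median of -0.01 over 33 genes (camera adjusted p = 0.871), with the oocyte survival gene Bcl2l10 at 2254 ± 270.1 and 2602 ± 146 and Cflar at 11.5 ± 1.59 and 15.7 ± 0.654. Autophagy genes had a median of -0.08 over 58 genes (camera adjusted p = 0.871), with Tsc2 at 24.1 ± 2.12 and 35.5 ± 2.55 and Atg13 at 19.6 ± 0.657 and 12.6 ± 2.20. Heat shock genes had a median of -0.01 over 40 genes (camera adjusted p = 0.871), with Hspa1a at 34.1 ± 2.10 and 41.9 ± 1.86 and Hspa14 at 76.4 ± 22.5 and 60.0 ± 4.92.

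The chromatin, division and metabolism lists gave the same outcome. DNA methylation genes had a median of 0.01 over 23 genes (camera adjusted p = 0.871), with Mbd1 at 2.81 ± 0.781 and 1.38 ± 0.673 and Tet1 at 3.60 ± 0.00261 and 2.13 ± 0.823. Histone-modifying enzymes had a median of -0.04 over 83 genes (camera adjusted p = 0.871), with the deacetylase Sirt7 at 15.1 ± 1.72 and 9.75 ± 2.65 and the demethylase Kdm3a at 23.9 ± 2.89 and 17.02 ± 2.74. Cell cycle genes had a median of -0.04 over 84 genes (camera adjusted p = 0.966), with Cdk1 at 96.1 ± 39.0 and 138 ± 40.6 and Anapc11 at 26.5 ± 4.53 and 17.3 ± 3.91. Proteasome genes had a median of -0.06 over 42 genes (camera adjusted p = 0.966), with Psmc2 at 26.7 ± 5.03 and 19.3 ± 2.44 and Psmc3 at 29.8 ± 7.79 and 40.1 ± 5.85. Splicing genes had a median of -0.07 over 63 genes (camera adjusted p = 0.871), with Srsf5 at 71.2 ± 17.3 and 49.5 ± 2.54 and Sf3a3 at 23.4 ± 4.76 and 14.5 ± 4.24. Glycolysis and citric acid cycle genes had a median of -0.10 over 48 genes (camera adjusted p = 0.871), with Pdk1 at 6.41 ± 1.504 and 11.9 ± 2.27 and Pdhb at 81.2 ± 16.8 and 58.4 ± 5.90. Lipid metabolism genes had a median of -0.02 over 49 genes (camera adjusted p = 0.966), with the carnitine carrier Slc25a20 at 15.4 ± 0.0937 and 9.47 ± 2.08 and Scd3 at 1.19 ± 0.565 and 3.14 ± 0.886. Mitochondrial dynamics genes had a median of -0.06 over 30 genes (camera adjusted p = 0.966), with the protease genes Clpp at 10.1 ± 0.529 and 4.29 ± 1.08 and Oma1 at 7.54 ± 2.46 and 2.85 ± 0.481.

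Markers of other cell types were mostly under the filter. The filter kept 7 of 36 cumulus and granulosa genes, 7 of 30 sperm genes, 8 of 18 blood and immune genes and 5 of 15 oviduct genes. Cumulus markers had a median log2 change of -0.13 (camera adjusted p = 0.871), with Serpine2 at 48.0 ± 12.0 and 39.3 ± 8.36 and Tnfaip6 at 1.95 ± 0.944 and 1.01 ± 0.911. Sperm transcripts had a median of -0.51 (camera adjusted p = 0.645), with Pgk2 at 5.97 ± 1.15 and 2.57 ± 2.48 and Oaz3 at 4.55 ± 2.90 and 2.17 ± 0.273. Blood and immune markers had a median of -0.37 (camera adjusted p = 0.156), with Cd74 at 9.09 ± 5.24 and 4.55 ± 1.17 and Hba-a2 at 2.84 ± 2.39 and 1.04 ± 0.640. Oviduct markers had a median of 0.03 (camera adjusted p = 0.966), with Krt8 at 2.83 ± 2.05 and 1.32 ± 0.277 and Clu at 2.29 ± 1.74 and 3.54 ± 1.06.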

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

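A fit without the variance trend and the alternatives for the count at an unadjusted p were chosen after the data were seen. The count of 0 changed genes held under the other settings of the limma fit except without PNMC replicate 1, where 1 gene passed (Gm13103, also the 1 gene at a 2-fold change), so the range over libraries left out was 0 to 1. The count at an unadjusted p ranged from 525 to 752 with a library left out and was 210 of 5675 genes under the stricter filter. The number of gene lists that passed was 4. It was 0 with no filter, 0 with the replicate block, 0 with an estimated correlation, 0 with fry and 2 after median scaling, and ranged from 1 to 6 with a library left out. Directions of lists here are those of camera's test, relative to other genes, and a median can keep its sign. The ribosomal protein list turned direction under the replicate block (median -0.0129) and without PNMC replicate 3 (median -0.0129), 2 settings that use the same 4 libraries for the contrast. Lists that passed only under some alternative also turned: mitochondrial genes with no filter (-0.0439), after median scaling (0.0321), without control replicate 1 (0.034) and without PNMC replicate 1 (0.0402). Ribosome biogenesis turned without control replicate 1 (0.00428), and the 2-cell programme without control replicate 1 (-0.0147) and without PNMC replicate 1 (0.00518). Of the named genes, Clu turned without control replicate 1 (log2 change -0.018, range to 1.11 with a library left out), and the other 732 gene results kept their direction and side of the threshold, apart from Gm13103. With a library left out, medians ranged from -0.283 to -0.0129 for ribosomal proteins, -0.118 to 0.0402 for mitochondrial genes, -0.214 to 0.00428 for ribosome biogenesis and -0.117 to 0.00518 for the 2-cell programme. The cause was not tested. Nothing in the labels says that the replicate numbers pair the libraries, and the third PNMC library has no partner. Deviations from the group means correlated at -0.0585 for number 1 and -0.0433 for number 2. These values cannot decide on pairing, because the deviations of 2 controls mirror each other: PNMC library 1 correlated at 0.0585 with control library 2. With the block the count of changed genes was 0. The count-based alternatives were not run, since the table holds no counts. The number of libraries and the unknown depth limit what low genes can show.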

Other observations

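The tests of the gene count and of the ribosomal protein, respiratory chain and maternal lists on splits of the libraries, of overlap between groups over the lists, of the stress response list without control library 2, and of shared sequence against level across genes were chosen after the result was seen.

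In the values as deposited, whose scaling is unknown, the median log2 change was -0.10 for the 5340 genes with a mean level under 5, -0.07 from 5 to 20, -0.02 from 20 to 100 and 0.02 for the 750 genes of at least 100. Maternal transcripts were among the abundant genes, with a mean value of 571 in controls and 625 after PNMC over the list.

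The ribosomal protein and respiratory chain lists were lower after PNMC and the maternal list higher relative to other genes at camera's preset correlation, the maternal list not under quantile normalisation (median -0.01), and none of them with an estimated correlation (adjusted p = 0.971 with an estimated correlation for each). A trend with transcript length or level stays open. Of 10000 random lists matched on both, 0.0% had a median as low as the ribosomal proteins and 0.02% as low as the respiratory chain. A median as high as the maternal list came from 1.01%. These lists were drawn gene by gene, which decides nothing for lists whose members vary together. Quantile normalisation ended the maternal call (limma camera adjusted p = 0.862). It kept the ribosomal protein call (median -0.132, limma camera adjusted p = 0.00532) and the respiratory chain call (median -0.149, limma camera adjusted p = 0.00548), but does not address length. The respiratory chain call may rest on control library 2, since the p of limma's camera was 0.746 without it, but it ended without PNMC library 3 as well (limma camera adjusted p = 0.858), as did the ribosomal protein call (adjusted p = 0.976), while camera's p without control library 2 was 0.000126 for ribosomal proteins and 9.47e-05 for the maternal list. The estimated correlation was 0.455 among ribosomal proteins, 0.262 in the respiratory chain list and 0.0529 in the maternal list, and camera's p was 0.00122 for them in the real split against 5.36e-20 for the lowest of the others, 0.000902 against 1.3e-09 for the respiratory chain, and 0.00156 against 0.00476 for the maternal list. The real split of the 5 libraries gave 4 lists and 636 genes at an unadjusted p, and the highest of the others gave 5 lists and 1013 genes. Counts at least as high as the real ones came from 5 of the 10 splits for lists and 5 for genes, the real split included. A camera p as small came from 7 of the 10 for ribosomal proteins, 6 for the respiratory chain and 1 for the maternal list. The 10 splits are too few for a share under 0.05.

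The stress response list, with Ddit3, Sdf2l1 and Hspa5, was lower in all 3 PNMC libraries than in both controls, as were the glycolysis, sperm and blood and immune lists (4 of 28 lists, or 14.3%, where chance gives 20%), and its estimated correlation was -0.00348. Random lists matched on length and level shifted less, with a typical median of -0.0312 against -0.14 for the list, and 0.35% were as low. The list was followed up because it passed among 28 lists, and this share is not adjusted for that choice. The share therefore does not decide on length and level as the cause. Control library 2 as the cause is argued against by a camera p of 0.00666 without it. The real split gave a camera p of 0.00457 and the lowest of the others 0.0149, and 10 splits are too few for a share under 0.05. The unadjusted p was 0.0439 with an estimated correlation (adjusted p = 0.971 with an estimated correlation) and 0.00765 with fry (adjusted p = 0.214), and the camera call ended after median scaling (adjusted p = 0.0894). None of these tests decides between an effect of PNMC, a difference between cultures, technical spread between libraries and chance.

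Gapdh was listed at 1.27 on average over the 5 libraries, while Aldoa averaged 187, Pkm 239.6 and Ldhb 1031 in the same pathway, and Aldoc 0.566, Hk1 0.879 and Pdk2 2.26, with 0.0%, 2.0% and 0.0% of their sequence words shared, were also low; these 6 genes were chosen after their values were seen. A candidate explanation is reads shared with near-identical copies: 62.6% of the 31-base words of Gapdh's coding transcripts also occur in transcripts of other genes, against a median of 1.0% over the 48 glycolysis and citric acid cycle genes, and 133 other genes share at least 100 word matches with it. Sharing alone did not track low levels across genes, which are not independent replicates: Spearman's rho between the shared share and the level was 0.351 over those 48 genes (permutation p = 0.0143, adjusted over the 2 correlations 0.0286) and -0.048 over 82 ribosomal protein genes (permutation p = 0.67, adjusted 0.67). The levels these genes would have with no reads shared are unknown. The correlations therefore decide neither for nor against shared reads as the cause of Gapdh's low value. No biological explanation was tested, and Gapdh is no usable reference level in this table.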
